A study of Homo sapiens with 37 samples.

How the data were processed

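Small RNA was sequenced from samples of people with ulcerative colitis (UC, 10 samples), Crohn's disease (CD, 9 samples) or diverticular disease (control, 18 samples), per the labels. The labels give the diagnosis of each sample and no batch. They also call the samples epithelial cells, while the description of the design speaks of colonic mucosa. The text says mucosa after that description, and which was sequenced is not settled.

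The submitters' processing notes name Novoalign for alignment, DESeq for the comparison and hg19 as the genome. No version is given for any of them. Per the file headers the genome version is a human assembly that corresponds to hg19, and the headers also give the summed reads of each arm. The deposited sheets used here hold whole read counts per region in each library, and the regions are 939 miRNA hairpins and 402 snoRNAs, 1341 in all. The authors also deposited a score per region, which is minus 10 times the log10 of their p and of its Benjamini-Hochberg adjustment. Their other deposited column is a log2 ratio of the summed reads of the disease and control arms plus 1 read, after a scaling that the file headers do not describe. The adjusted score was checked against an adjustment of the p score and ranked the regions in the same order (rank correlation 1.0 in both sheets). How reads were trimmed, filtered or assigned to regions is not stated.

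Counts were read from the sheet that sets UC against control and the sheet that sets CD against control. The 18 control libraries are in both sheets and 0 of their values differed. A region left blank in a sheet was taken as 0 reads. There were 379 blank regions in the UC sheet and 399 in the CD sheet, and the controls had 0 reads in the 32 regions that were blank in 1 sheet only. UC replicate 3 has 2 libraries, which were summed. Another sheet holds 11 libraries that match no sample of the series and was left out, together with sheets that repeat values. No region lies on the Y chromosome.

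Overlapping regions were compared to see how strand was used. Of 15 pairs of miRNA regions on opposite strands with reads, 9 had equal counts in each of the 37 libraries, and mir-3065 and mir-338 had 36944 and 36941 reads in total. Reads from opposite strands were thus not told apart in these pairs, and the text calls such a pair 1 signal, but both regions stay in the tests and in every count of miRNAs. The regions mir-1201 and SNORD126, and mir-1259 and HBII-99B, had equal counts in all libraries.

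The miRNA regions were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling factors, filterByExpr by group, a quasi-likelihood fit of group means over all 37 libraries, and Benjamini-Hochberg adjustment over the 314 miRNAs tested. The threshold was an adjusted p of 0.05. A further 320 miRNAs had reads but did not pass the filter, and the tested ones held 99.99% of the miRNA reads. The common biological coefficient of variation was 0.64, and scaling factors ran from 0.44 to 1.75. Normalised levels are CPM from edgeR on the scaled library sizes, given as mean ± SD over libraries, and changes are log2 fold changes ± SE. The snoRNA regions were tested the same way in a further fit that also held the miRNAs, with adjustment over the snoRNA regions.

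Before the data were examined, 13 lists of miRNAs were fixed: markers of colonic epithelium, leukocytes, red blood cells, smooth muscle, fibroblasts with endothelium, and neurons, inflammation-induced miRNAs, the miR-17-92 clusters, the let-7 family, the imprinted 14q32 cluster, the HOX clusters, miRNAs recalled as the study's own candidates, and the 2 miRNAs that a deposited sheet is named for. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. The numbers of members past the threshold are given over all miRNAs tested and adjusted over the list alone. Copies of 1 miRNA at several loci count as separate members.

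The named miRNAs follow a rule that was also fixed before the data were examined. In each comparison it takes, among those past the threshold with a group mean of at least 50 CPM, the 10 with the largest positive and the 10 with the largest negative change. It adds the 3 most abundant miRNAs, mir-155 and mir-146a, up to 4 members of each list with the smallest adjusted p, the 5 with the smallest adjusted p between UC and CD, and the recalled candidates. Names outside it, chosen after their values were seen, are marked where they stand.

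Single values were compared between groups with two-sided permutation tests of the difference in means, computed with numpy 2.4.6. They were exact where a group holds fewer than 10 libraries and used 100000 resamples between UC and control. Benjamini-Hochberg adjustment was over the 3 comparisons of each measure. Effects shared by UC and CD were set against 100 simulations of unchanged groups that share the same controls, and of unchanged groups with split controls. The grouping was set against 100 splits of the samples, the real one included. The procedure was tested on simulated data with changes of 2-fold and 4-fold. For UC against control it recovered 47.2% of the 2-fold and 94.2% of the 4-fold changes, and 6.3% of its calls were unchanged miRNAs. The recovered shares were 58.5% and 96.1% for CD against control and 42.2% and 86.4% for UC against CD, with 3.6% and 2.8% of calls on unchanged miRNAs.

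The alternatives changed the scaling, the test (DESeq2 1.42.0 and limma-voom), the filter, the threshold, the samples in the fit, the summing of copies and the depth, and left out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the remaining steps. Coordinates are hg19 as the deposited files give them. What lies at a locus was looked up by symbol in GENCODE release 29, where 112 of 120 named features were found.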

Results

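Reads were counted in 939 miRNA hairpins and 402 snoRNAs in colonic mucosa of 10 people with UC, 9 with CD and 18 controls with diverticular disease. Total reads per library had a median of 1891520 in UC (range 273310 to 8238302), 920747 in CD (462201 to 2794353) and 3759436 in controls (2204774 to 7792918). The mean log10 total was 6.29 ± 0.456 in UC, 6.03 ± 0.264 in CD and 6.59 ± 0.153 in controls (SD). It was lower in CD than in controls by an exact permutation test (difference −0.567, adjusted p = 7.04e-06) and lower in UC than in controls by a permutation test (difference −0.308, adjusted p = 0.0157). Between UC and CD the difference was 0.259 (exact permutation test, p = 0.155). The miRNA regions took 96.5% ± 0.976 of the reads in UC, 96.7% ± 1.89 in CD and 97.6% ± 0.966 in controls. The most abundant were mir-143, mir-21 and mir-192, which together held 57.8% ± 6.4, 53.6% ± 11.6 and 53.8% ± 8.6 of the miRNA reads in UC, CD and controls. The files name hairpins, not mature strands, and the prefix hsa- of each name is left out here.

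In UC mucosa, 6 of 10 leukocyte hairpins and 7 of 9 inflammation-induced hairpins were higher than in controls, and 8 of 11 hairpins of the colonic epithelium were lower. As sets, the 3 lists passed with the preset correlation and not with an estimated one (adjusted p = 0.0592, 0.0511 and 0.0592 with an estimated correlation). The largest rise among abundant hairpins was in mir-31, which inflammatory signals induce in gut epithelium, with 211 ± 431 CPM in UC against 6.07 ± 7.67 in controls (log2 fold change 5.14 ± 0.85, or 3.70 without UC replicate 2, still past the threshold). It was uneven: UC replicates 2 and 6 reached 10.4 and 8.6 log2 CPM, while replicates 3, 8 and 9 (3.6, 1.8 and 2.0) lay below the highest control (4.9). The other UC libraries lay between 5.0 and 6.6. The myeloid mir-223 rose by 2.28 ± 0.36, mir-142, found in all blood cell lineages, by 2.40 ± 0.56, and mir-155, which activated leukocytes make, by 1.67 ± 0.28. The largest falls among abundant hairpins were in mir-194-2 (−3.21 ± 0.65), mir-375 (−2.46 ± 0.54) and mir-192 (−2.11 ± 0.50), all abundant in gut epithelium. Of 314 miRNAs tested, 46 were higher and 37 lower in UC, but 39 and 39 with RLE scaling and 26 and 46 with upper-quartile scaling, chosen after seeing the data, so which direction held more is not settled.

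The colonic epithelium list had 8 of 11 members lower and 0 higher, the same counts adjusted over the list alone. They were mir-194-2, mir-375, mir-192, mir-203 and the mir-200 family members mir-200a, mir-200b, mir-200c and mir-429, which keep ZEB repressors low in epithelial cells. Of these, mir-203, mir-200a, mir-200b and mir-200c are outside the naming rule for UC and were chosen after their values were seen. In mir-375 the level was 9282 ± 10720 CPM in UC and 51240 ± 41720 in controls, below the control median in 10 of 10 UC libraries. The list was lower as a set (adjusted p = 7.41e-08; adjusted p = 0.0592 with an estimated correlation). Per library the mean log2 CPM of its members was 11.9 ± 1.37 in UC and 13.7 ± 0.460 in controls, a difference of −1.82 (permutation test, adjusted p = 7.5e-05). This and the other tests of list means per library were chosen after seeing the data.

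Of 10 leukocyte hairpins, 6 rose and 0 fell, with the same counts adjusted over the list alone. They were mir-223, mir-142, mir-155, mir-146a, mir-150 and mir-181a-1, and the list was higher as a set (adjusted p = 0.00316; adjusted p = 0.0592 with an estimated correlation). In mir-223 the level was 2379 ± 2835 CPM in UC and 489 ± 271 in controls. UC replicate 5 stood apart with 10420 CPM, and without it the change was 1.60, still past the threshold. The mean of the list per library differed by 0.925 (permutation test, adjusted p = 3e-05). Outside the naming rule, mir-150 and mir-181a-1 were chosen after their values were seen.

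The inflammation-induced list had 7 of 9 members higher and 1 lower, again the same counts adjusted over the list alone. It was higher as a set (adjusted p = 0.000723; adjusted p = 0.0511 with an estimated correlation), and 2 of its risers, mir-155 and mir-146a, are also in the leukocyte list. Besides these, mir-31, mir-135b (1.41 ± 0.31), mir-146b, mir-132 and mir-212 rose, the last 3 chosen after their values were seen, outside the naming rule. The member that fell was mir-147b, known as a product of stimulated macrophages (−1.78 ± 0.48, adjusted p = 0.00613, lower in 10 of 10 libraries), and mir-21 did not pass (0.67 ± 0.36, adjusted p = 0.167). The list mean per library differed by 1.10 (permutation test, adjusted p = 6e-05).

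Erythroid hairpins moved in the same samples. In that list 2 of 6 rose and 0 fell, with the same counts adjusted over the list alone: mir-451, which red cells carry, by 2.26 ± 0.50 and mir-486 by 1.72 ± 0.40 (adjusted p of the list 0.0171; adjusted p = 0.27 with an estimated correlation). Its mean per library differed by 1.01 (permutation test, adjusted p = 0.00336). The let-7 family, high in differentiated cells, had 2 of 12 members higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00290; adjusted p = 0.362 with an estimated correlation). These were let-7i (1.72 ± 0.34) and let-7c (2.82 ± 0.71), and let-7c was carried by UC replicate 9: without it the change was 0.81 and no longer past the threshold. The mean of the let-7 list per library differed by 0.895 and did not pass (permutation test, adjusted p = 0.0642).

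The other lists were not past the threshold as sets. Smooth muscle had 0 of 4 members past it (adjusted p = 0.784), fibroblast and endothelium 1 of 10 higher (mir-125b-1, adjusted p 0.243), and neuronal 0 of 9 (adjusted p = 0.337), the same adjusted over the list alone. The miR-17-92 clusters, active in proliferating cells, had 3 of 14 higher and 1 lower, or 4 and 2 adjusted over the list alone (adjusted p = 0.476). The 14q32 cluster had 5 of 36 higher and 1 lower, and 0 adjusted over the list alone (adjusted p = 0.242). The HOX clusters had 2 of 5 lower, mir-196a-1 and mir-196a-2, also adjusted over the list alone (adjusted p = 0.157). Of the recalled study candidates, which were chosen on these samples and are not independent evidence, mir-194-2 and mir-147b fell and mir-1826 did not pass (0.19 ± 0.38), the same counts adjusted over the list alone, with an adjusted p of 0.0776 for the list. Both miRNAs that a deposited sheet is named for, mir-155 and mir-146a (1.66 ± 0.36), rose. The median and the test differed in sign for the smooth muscle list (median 0.21, tested as lower) and the miR-17-92 clusters (median −0.15, tested as higher).

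Outside the lists, mir-424 of the mir-15/16 seed family rose by 1.42 ± 0.27, and mir-552 (−1.84 ± 0.40), mir-28 (−1.76 ± 0.39), mir-3065 with mir-338 (1 signal, −1.39 ± 0.41) and mir-378 (−1.27 ± 0.35) fell. In hg19, mir-31 lies on chromosome 9 from 21512114 to 21512184, in an intron of MIR31HG. On chromosome 21, mir-155 spans 26946292 to 26946356 in an exon of MIR155HG, and mir-223 spans 65238712 to 65238821 on chromosome X. The neighbours mir-192 (64658609 to 64658718) and mir-194-2 (64658827 to 64658911) lie on chromosome 11 in exons of MIR194-2HG. On chromosome 15, mir-147b spans 45725248 to 45725327 in a UTR exon of C15orf48. The change of mir-136 (−1.92 ± 0.71) did not stay past the threshold when any of 10 single libraries was left out, nor did that of mir-196a-2 for any of 20 or mir-196a-1 for any of 4. Nor did mir-3065 with mir-338 pass with limma-voom (−1.03) or mir-429 with library totals alone (−1.07). With library totals alone 51 miRNAs passed in place of 83, and with equal depth 49 of 204 did.

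**Figure D1:**
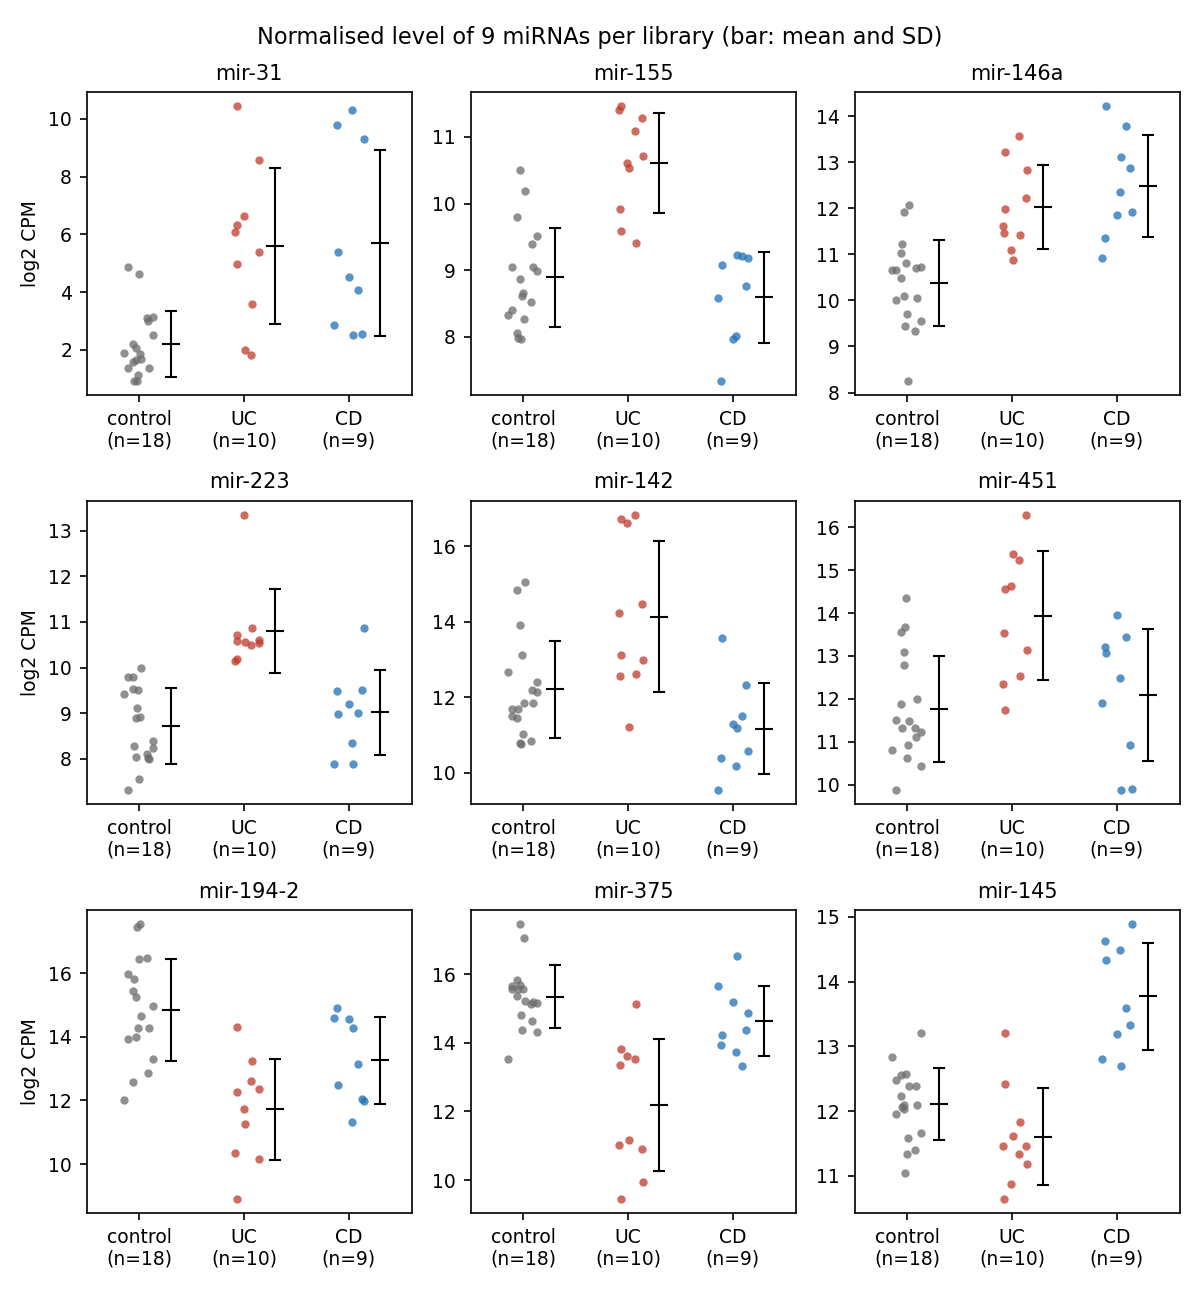
Normalised level of 9 hairpins in each library, in log2 CPM, with 1 point per library and bars for mean and SD in controls (n = 18), UC (n = 10) and CD (n = 9). Levels of mir-155 in all 10 UC libraries lie above the control median, while mir-145 is above the control median in all 9 CD libraries.

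In CD mucosa, 5 of 11 epithelial hairpins were lower than in controls, and the leukocyte list did not pass its test. The epithelial list passed as a set with the preset correlation but not with an estimated one (adjusted p = 0.548 with an estimated correlation). The largest rise among abundant hairpins was again in mir-31, with 316 ± 476 CPM against 6.07 ± 7.67 (log2 fold change 5.71 ± 0.87, or 5.06 without CD replicate 7, still past the threshold). It was carried by part of the samples: CD replicates 2, 4 and 7 reached 9.3, 9.8 and 10.3 log2 CPM. Replicates 3, 5, 6, 8 and 9 (4.5, 2.5, 4.1, 2.5 and 2.9) lay below the highest control (4.9), and replicate 1 was at 5.4. Above the control median in 9 of 9 CD libraries were mir-146a (2.22 ± 0.37), a brake on NF-kB signalling, and mir-145 (1.77 ± 0.28), a smooth muscle hairpin with 16110 ± 8794 CPM in CD and 4719 ± 1827 in controls. The largest falls among abundant hairpins were in mir-552 (−2.45 ± 0.44), mir-107 (−2.14 ± 0.65) and mir-194-2 (−1.87 ± 0.63). Of these, mir-107 was not past the threshold with limma-voom (−1.38) or with library totals alone (−1.58). Nor was mir-194-2 in these 2 settings (−1.28 and −1.34), with no filter on low counts (−1.89) or without the libraries under 600000 reads (−1.69). Of 314 miRNAs, 26 were higher and 21 lower in CD, but 24 and 41 of 294 with copies summed, and 21 and 29 at a false discovery rate of 0.10 and 2-fold, so which direction held more is not settled.

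The colonic epithelium list had 5 of 11 members lower and 0 higher, also adjusted over the list alone: mir-203 (−1.66 ± 0.40), mir-429 (−1.62 ± 0.40), mir-200a (−1.60 ± 0.37), mir-141 (−1.28 ± 0.35) and mir-194-2. With library totals alone none of these 5 stayed past the threshold, at −1.28, −1.13, −1.14, −0.94 and −1.34 in the same order. The list was lower as a set (adjusted p = 8.96e-05; adjusted p = 0.548 with an estimated correlation). Per library its mean was 12.4 ± 0.369 in CD against 13.7 ± 0.460, a difference of −1.29 (exact permutation test, adjusted p = 3.2e-06). The abundant mir-192 did not pass (−1.01 ± 0.49, adjusted p = 0.153), and neither did mir-21 (−0.59 ± 0.38) or mir-143 (0.64 ± 0.42).

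In the smooth muscle list 2 of 4 rose, mir-145 and the low-level mir-1-1 (1.45 ± 0.50), also adjusted over the list alone, and the list was not past the threshold (adjusted p = 0.0936), nor was the difference of its mean per library (0.835, exact permutation test, adjusted p = 0.0665). The rise of mir-1-1 did not stay past it when any of 8 single libraries was left out. On chromosome 5, mir-145 (148810209 to 148810296, intron) and mir-143 (148808481 to 148808586, exon) are both annotated in CARMN. The difference of log2 mir-145 and log2 mir-143 within a library was 1.40 higher in CD than in controls (exact permutation test, adjusted p = 0.00152).

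The inflammation-induced list had 2 of 9 higher, mir-31 and mir-146a, and 3 adjusted over the list alone (adjusted p = 0.812), and its mean per library differed by 0.361 (exact permutation test, adjusted p = 0.0209). The rise of mir-31 alone is large enough to make up this difference, and the median change of the list was −0.30. The difference is thus no rise of the list as a whole. The leukocyte list had 1 of 10 higher, mir-146a (adjusted p = 0.812), with mir-155 at −0.37 ± 0.31 and mir-142 at −1.19 ± 0.63. Its mean per library differed by 0.081 (exact permutation test, adjusted p = 0.600). Erythroid hairpins had 0 of 6 past the threshold (adjusted p = 0.507), fibroblast and endothelium 0 of 10 (adjusted p = 0.507), neuronal 0 of 9 (adjusted p = 0.885) and the HOX clusters 0 of 5 (adjusted p = 0.885). The 14q32 cluster had 4 of 36 higher, mir-655, mir-134, mir-495 and mir-432 (adjusted p = 0.0936). The call of mir-495 ended without CD replicate 3 (0.82), without CD replicate 7 (0.87) and in 3 other settings. The let-7 family had 1 of 12 higher, let-7i (1.28 ± 0.35, adjusted p of the list 0.565), and the miR-17-92 clusters 1 of 14 lower, mir-92a-2 (adjusted p = 0.734). Counts adjusted over the list alone were the same for these lists. The median and the test differed in sign for the inflammation-induced (median −0.30), leukocyte (−0.16), neuronal (−0.06) and let-7 (−0.24) lists, all tested as higher, none past the threshold.

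Of the recalled study candidates, chosen on these samples and not independent evidence, mir-1826 rose (1.77 ± 0.38, or 1.15 without CD replicate 1, still past the threshold) and mir-194-2 fell, and mir-147b did not pass (−0.65 ± 0.47), with an adjusted p of 0.885 for the list and the same counts adjusted over the list alone. The candidates mir-383 and mir-615 had too few reads to be tested: mir-383 had 11 reads in UC, 19 in CD and 3 in controls, and mir-615 had 9, 104 and 14. Of the miRNAs that a deposited sheet is named for, only mir-146a passed in CD. Other rises were in mir-424 (1.60 ± 0.27), mir-130a (1.39 ± 0.21), mir-1975 (1.36 ± 0.33), mir-26a-2 (1.18 ± 0.27) and mir-134 (1.07 ± 0.28). Other falls were in mir-190 (−1.66 ± 0.37), mir-191 (−1.29 ± 0.31) and mir-30b (−1.20 ± 0.26). Entries mir-1826 (chromosome 16, 33965508 to 33965592) and mir-1975 (chromosome 7, 148638580 to 148638654) are known as pieces of structural RNA that were withdrawn from the miRNA registry. The CD samples carry another title series than the UC and control samples, so a separate preparation and the diagnosis cannot be told apart. With library totals alone 28 miRNAs were higher and 1 lower in CD, at a median change of 0.28 over all miRNAs, and the falls of mir-194-2, mir-203, mir-429, mir-200a, mir-141, mir-107, mir-190, mir-191, mir-30b and mir-92a-2 were then not past the threshold. Leaving out any of 8 single libraries also ended the call of mir-194-2.

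**Figure D2:**
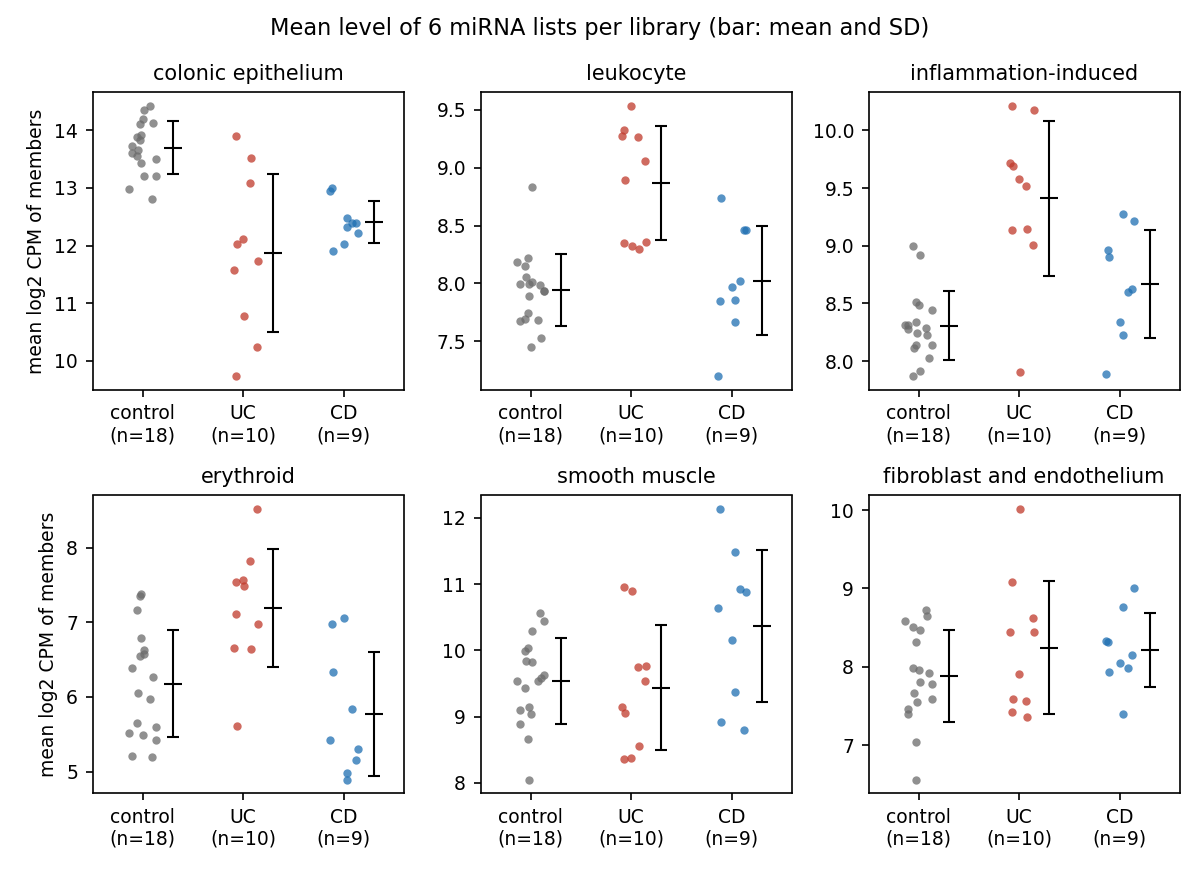
Mean log2 CPM of the members of 6 lists in each library, with 1 point per library and bars for mean and SD in controls (n = 18), UC (n = 10) and CD (n = 9). The epithelium list averages 13.7 in controls, 11.9 in UC and 12.4 in CD, and the leukocyte list averages 7.94, 8.87 and 8.02.

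Between the diseases, 5 of 9 inflammation-induced, 4 of 6 erythroid and 4 of 10 leukocyte hairpins were higher in UC, and mir-145 was higher in CD. The leukocyte list did not pass as a set (adjusted p = 0.0505), and the other 2 lists passed only with the preset correlation (adjusted p = 0.187 for each with an estimated correlation). The largest difference among abundant hairpins was in mir-142, with 39880 ± 47820 CPM in UC and 3297 ± 3552 in CD (log2 fold change 3.60 ± 0.76). In all 10 UC libraries mir-155 (2.04 ± 0.36), mir-223 (1.90 ± 0.44), mir-146b (1.68 ± 0.33) and mir-454 (2.31 ± 0.37) were above the CD median. Lower in UC were mir-145 (−2.17 ± 0.34) and mir-375 (−1.81 ± 0.57). Of 314 miRNAs, 35 were higher and 28 lower in UC than in CD. With RLE scaling 26 were higher and 35 lower, so which direction held more is not settled. The UC and CD samples carry different title series. In every difference between UC and CD a separate preparation thus cannot be told apart from the diagnosis.

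The erythroid list had 4 of 6 higher in UC, or 5 adjusted over the list alone. The 4 were mir-486 (3.0 ± 0.60, or 3.75 without CD replicate 3, still past the threshold), mir-451 (1.92 ± 0.62), mir-16-1 (0.83 ± 0.28) and mir-16-2 (0.77 ± 0.28). The calls of mir-16-1 and mir-16-2 ended when any of 17 and any of 28 single libraries was left out, and in 11 and 12 other settings. The list was higher as a set (adjusted p = 0.00574; adjusted p = 0.187 with an estimated correlation), and its mean per library differed by 1.42 (exact permutation test, adjusted p = 0.00336). The inflammation-induced list had 5 of 9 higher, mir-155, mir-146b, mir-21 (1.27 ± 0.43), mir-132 and mir-212, also adjusted over the list alone (adjusted p = 0.0195; adjusted p = 0.187 with an estimated correlation). With ranks this list did not pass (adjusted p = 0.0749). Its mean per library differed by 0.740 (exact permutation test, adjusted p = 0.0209). The leukocyte list had 4 of 10 higher, or 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0505), and its mean per library differed by 0.844 (exact permutation test, adjusted p = 0.00279). The epithelium list had 1 of 11 lower, mir-375 (adjusted p = 0.166), and its mean per library differed by −0.538 (exact permutation test, adjusted p = 0.273).

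Smooth muscle had 1 of 4 lower, mir-145 (adjusted p = 0.0814), and fibroblast and endothelium 0 of 10 past the threshold (adjusted p = 0.854). The let-7 family had 2 of 12 higher, let-7e (1.59 ± 0.49) and let-7g (adjusted p = 0.0796), the miR-17-92 clusters 1 of 14 higher, mir-106b (adjusted p = 0.173), and the HOX clusters 0 of 5 (adjusted p = 0.115). These counts were the same adjusted over the list alone. Neuronal hairpins had 1 of 9 lower, mir-129-2 (adjusted p = 0.320), and the 14q32 cluster 1 of 36 higher, mir-654, and 1 lower, mir-136 (adjusted p = 0.480), and both lists had 0 adjusted over the list alone. Of the recalled candidates, not independent evidence, mir-1826 was lower in UC (−1.58 ± 0.46) and mir-194-2 (−1.34 ± 0.65) and mir-147b (−1.13 ± 0.52) did not pass, while all 3 did adjusted over the list alone (adjusted p of the list 0.0857). Of the miRNAs that a deposited sheet is named for, mir-155 passed and mir-146a did not (−0.56 ± 0.43).

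Further differences higher in UC were mir-106b (1.70 ± 0.52), mir-182 (1.5 ± 0.37) and mir-181a-1 (1.47 ± 0.40). Lower in UC were mir-577 (−1.58 ± 0.44), mir-149 (−1.41 ± 0.33), mir-3065 with mir-338 (1 signal, −1.37 ± 0.46), mir-590 (−1.35 ± 0.30) and mir-378 (−1.34 ± 0.39). Some calls ended when 1 library was left out: mir-106b was 0.75 without UC replicate 2 and 1.44 without CD replicate 2, mir-1826 was −0.95 and mir-378 −1.02 without CD replicate 1, and mir-375 was −1.43 and let-7e 1.47 without CD replicate 5, none of them past the threshold. The size itself changed little for let-7e and for mir-106b without CD replicate 2, where the call was lost rather than the difference. The difference of mir-223 was 1.21 without UC replicate 5 and stayed past it. Without UC replicate 2 mir-212 was 1.01 and did not pass. The count fell from 63 to 32 without CD replicate 5, to 40 without UC replicate 6 and to 41 without UC replicate 1. Leaving out any of 9 single libraries ended the call of mir-21, any of 5 that of mir-451 or of mir-338, any of 14 that of let-7g, any of 12 that of mir-129-2, any of 23 that of mir-654, and any of 3 that of mir-132. For mir-136 the difference was −1.90 without CD replicate 5 and −2.12 without CD replicate 9, neither past the threshold.

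Changes in UC and CD against the same controls were compared because a shared control makes them resemble each other. Across 314 miRNAs the log2 changes had r = 0.48, against 0.32 ± 0.06 (SD) in 100 simulations of unchanged groups, and miRNAs are not independent replicates. The covariance was 0.39 against 0.05 simulated, a difference of 0.34. With the controls split at random so that each disease had its own, r was 0.34 and 0.32, against 0.02 ± 0.07 and 0.01 ± 0.07 (SD) in 100 simulations of unchanged groups with controls split the same way, none of them above 0.19. The covariance was then 0.28 and 0.27, against 0.003 and 0.001 simulated. The simulations with split controls were added after seeing the data. All simulations drew each miRNA independently, while members of a list moved together (estimated correlation 0.44 for the epithelium and 0.61 for let-7). Their spread of r is thus too narrow, and they do not settle whether the observed r lies beyond chance. Higher in both diseases were 11 miRNAs and lower in both were 9, where independent calls would give 3.8 and 2.5, but calls against the same controls are not independent. With the controls split, higher in both were 4 against 1.7 for independent calls in the first pairing and 6 against 1.0 in the other, and lower in both were 3 against 1.9 and 2 against 1.3. The overlap of calls was not tested beyond these numbers. Names in this paragraph follow the rule in at least 1 of the 3 comparisons unless stated. The shared rises include mir-31, mir-146a, mir-424, let-7i and mir-130a, and the shared falls include mir-194-2, mir-200a, mir-203, mir-429, mir-552, mir-190 and mir-191. Only mir-454 was called in opposite directions (1.30 in UC and −1.0 in CD). Outside the naming rule, and chosen after its values were seen, mir-663 was higher in both (3.78 in UC and 4.56 in CD) at 12.2 ± 14.1 and 17.4 ± 15.6 CPM against 0.703 ± 0.614.

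**Figure D3:**
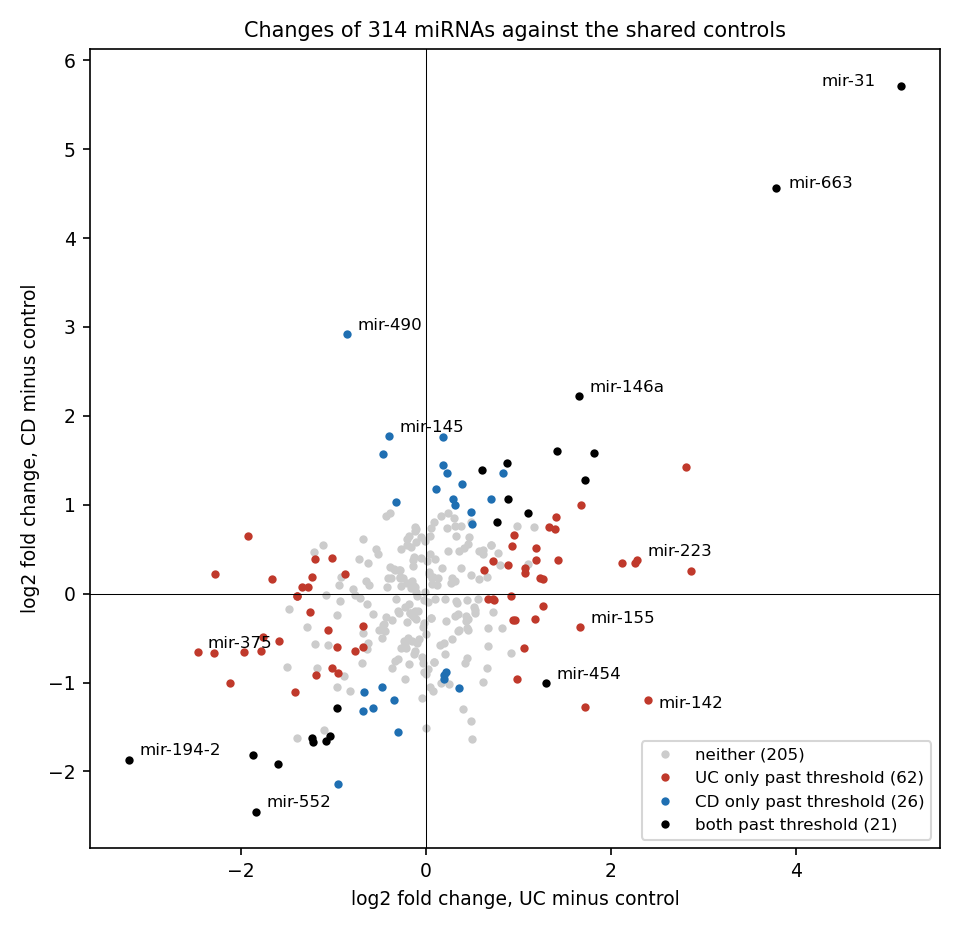
Log2 fold change of 314 miRNAs in UC (horizontal axis) and in CD (vertical axis) against the same controls, with 1 point per miRNA coloured by the comparison in which it passed the threshold. The 21 miRNAs past it in both fall in the quadrants of shared direction except mir-454, and r is 0.48.

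The authors' deposited values at a false discovery rate of 0.10 and a 2-fold change give 32 miRNAs for UC against control (22 higher, 10 lower) and 25 for CD (15 higher, 10 lower). Of these, 19 and 17 were also past the threshold in the fits described here, all in the same direction, and 13 and 7 were not tested here because of few reads. The fits here called 83 and 47 miRNAs, so most of these calls are not among the authors'. In the authors' values for UC, mir-31, mir-223, mir-142, mir-155 and mir-194-2 passed. The falls of mir-375 (false discovery rate 0.274), mir-192 (0.351), mir-429 (0.878) and mir-203 (0.896) did not, nor did the rise of mir-146a (0.222). Across the 314 tested miRNAs the authors' log2 ratios and the fitted changes had r = 0.99 for UC and 1.0 for CD. Both come from the same counts, so the shared direction and r are not independent evidence. Their UC sheet keeps the 2 libraries of UC replicate 3 in separate columns, which were summed here. For snoRNA regions their values give 9 higher and 6 lower for UC and 56 higher and 11 lower for CD, where the fit here gave 9 and 1 and 55 and 34, so the number lower is not settled. In their sheets mir-31 stood at 5.03 in UC and 5.52 in CD.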

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

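The tests of a lower epithelial share, of smooth muscle, of region length and of separate preparation for the snoRNAs were chosen after the result was seen, while the others were fixed before it. Outside the naming rule for UC, mir-203, mir-200a, mir-200b, mir-200c and mir-181a-1 were chosen after their values were seen, and so were the snoRNAs named.

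A first pattern is that epithelial hairpins were lower and leukocyte hairpins higher in UC than in controls, with 14 members of the lists past the threshold. After thinning every library to 262420 miRNA reads all 14 stayed past the threshold, so unequal read numbers do not account for these calls. Random thinning keeps the expected share of each hairpin in its library. It thus cannot exclude effects of how the shallow libraries were made. A lower share of epithelium should raise leukocyte and stromal hairpins alike. The leukocyte mean minus the stromal mean was higher in UC by 0.794 (permutation test, p = 0.0139). Most of this is the leukocyte rise already reported (0.925), since the stromal mean differed by 0.131 (permutation test, adjusted p = 0.635). A lower share that raises both alike thus does not account for the whole leukocyte rise, but the test was chosen with these results seen. For the fall of the epithelial hairpins a lower share stays open, since the test does not use them. With the mean of mir-451, mir-144 and mir-486 as a covariate for blood, 40 miRNAs were past the threshold in place of 83. Of the 14 members 8 stayed past it, so adjusting for these erythroid hairpins did not end those 8 calls. The covariate is an imperfect measure of blood and need not follow its leukocytes, so blood is not excluded for the 8. In the other 6 the call ended. Of these, mir-142 went from 2.40 ± 0.56 to 1.48 ± 0.62 and mir-203 from −1.21 ± 0.38 to −0.79 ± 0.38, so blood may add to these. The changes of mir-200a (−1.03 ± 0.34 to −0.99 ± 0.38), mir-200b (−1.01 ± 0.38 to −1.06 ± 0.42), mir-200c (−1.18 ± 0.39 to −1.14 ± 0.42) and mir-181a-1 (1.18 ± 0.33 to 1.10 ± 0.44) moved little while their SE grew. Infiltration by leukocytes and a change within leukocytes both stay open as biological explanations, as hypotheses only.

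A further pattern is that mir-145 was higher in CD than in controls with mir-143, of the same primary transcript, not past the threshold. The difference of their log2 levels was 1.40 higher in CD (exact permutation test, adjusted p = 0.00152) and −0.896 in UC (permutation test, adjusted p = 0.0266), which restates the pattern and excludes nothing. More smooth muscle in the CD samples stays open: of the 3 other smooth muscle hairpins 1 was past the threshold, mir-1-1 (1.45 ± 0.50), with mir-1-2 at 0.90 ± 0.44 and mir-143 at 0.64 ± 0.42. The list mean differed by 0.835 and did not pass (exact permutation test, adjusted p = 0.0665). Separate preparation of the CD libraries stays open: the same difference shifted by 0.51 between the 2 libraries of UC replicate 3, no CD or control sample has 2 libraries, and the CD samples carry their own title series. A diagnosis-linked change in processing of the transcript was not tested.

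Signals also appear in the snoRNA regions, which the comparisons of miRNAs do not use, and these are the last pattern. Of 232 regions, 9 were higher and 1 lower in UC than in controls, and 55 were higher and 34 lower in CD, among them U17a (4.12 ± 0.46) and U17b (4.02 ± 0.43), which act in rRNA processing, while U78 fell (−3.85 ± 0.72). The 55 regions had a median change of 1.89 before thinning to equal depth and 1.95 after it. Random thinning keeps the expected share of each region in its library. This median was thus bound to stay close, and it does not decide whether lower depth is the cause. More broken longer RNA in the CD libraries stays open: the change went up with region length (Spearman 0.32 across regions, which are not independent replicates, just past the bound of 0.3 set for it). Of 96 regions over 100 bases 37 were higher and 4 lower, against 18 and 30 of 136 shorter ones. The same correlation for the UC change was −0.19. Among the regions looked up, those with a SNORA symbol were longer than those with a SNORD symbol. Length thus cannot be told apart from the class of snoRNA, and the correlation does not decide whether RNA was broken. Separate preparation cannot be told apart from the diagnosis: 31 of the 46 of these regions that could be compared were over 2-fold apart between the 2 libraries of a UC sample, but so were 145 of all 221. Of the 31, all 31 were higher in the first library and 0 in the second. The direction of the other regions over 2-fold apart is not given. A shift common to all snoRNA regions thus cannot be told apart from one of these regions. Across regions the difference between the 2 libraries had r = 0.06 with the CD change and 0.07 with the UC change. No biological explanation was tested.

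The number of results past the threshold was set against 100 splits of the samples. For miRNAs only 1 split, the real one, gave as many in each comparison: 83 against at most 14 in the other splits for UC and control, 47 against at most 26 for CD and control, and 63 against at most 15 for UC and CD. This argues against chance, though 100 splits cannot show a share below 1 in 100. For snoRNA regions the same holds for CD (1 split, 89 against at most 44). In comparisons with CD the splits do not tell the diagnosis from the title series. For UC 3 splits gave as many snoRNA regions, which is under 5 in 100, but another split gave more than the real one (10 against at most 20), so the evidence against chance is weak. The same holds for lists between UC and control (3 splits, 5 lists against at most 6), and all 5 calls are lost with an estimated correlation. Chance cannot be excluded for the lists of CD against control (67 splits, 1 list against at most 7) or UC against CD (56 splits, 2 lists against at most 7).

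Single libraries stood apart from the others of their group in 10 of the 180 groups tested, and chance gives about 5 in 100. The gap to the nearest library over the range of the group is given for each, both taken in log2 CPM, while the levels in brackets are in CPM. In UC it was 0.51 for mir-106a in replicate 3 (4.48 CPM, others at least 16.2), 0.51 for mir-106b in replicate 2 (42870 CPM, others at most 7756), 0.54 for mir-135b in replicate 9 (22 CPM, others at least 82.0), 0.51 for mir-1975 in replicate 4 (2186 CPM, others at most 735), 0.78 for mir-223 in replicate 5 (10420 CPM, others at most 1859) and 0.50 for mir-590 in replicate 9 (45.7 CPM, others at least 81.6). In CD it was 0.73 for mir-18a in replicate 2 (58.0 CPM, others at least 158), 0.56 for mir-18b in replicate 8 (25.8 CPM, others at most 4.23), 0.53 for mir-1975 in replicate 9 (486 CPM, others at least 1054) and 0.56 for mir-655 in replicate 6 (94.8 CPM, others at most 40.1).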

How the results depend on the processing

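The settings with library totals alone, upper-quartile scaling, snoRNA regions kept in the fit, equal depth, a single library for the UC sample with 2, and removal of 2 libraries under 600000 reads were chosen after seeing the data. The pseudocount was not run, since the values are counts. The counts of miRNAs past the threshold (83 for UC and control, 47 for CD and control, 63 for UC and CD) stayed within 1.5 times except as follows. With library totals alone they were 51, 29 and 36, and with all libraries thinned to equal depth 49, 30 and 34, where only 204 miRNAs are tested. A covariate for blood gave 40 for UC and control. The DESeq2 Wald test gave 75 for CD and control with 454 tested. For UC and CD the count was 39 with no filter and 41 without the 2 shallow libraries. Leaving out single libraries gave 32 to 71 for UC and CD. Apart from the number of miRNAs or libraries left, the cause was not tested. Totals alone moved the median change of all miRNAs to 0.28 in CD and −0.18 between UC and CD, and upper-quartile scaling moved it to −0.24 in UC and −0.20 between UC and CD, so the balance of directions (26 higher and 46 lower in UC, 18 and 40 between UC and CD) depends on the scaling. It moved to −0.14 in UC and −0.20 in CD with snoRNA regions kept, to −0.14 in CD with copies summed and to 0.11 in CD with DESeq2.

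Lists past the threshold numbered 5, 1 and 2, and 0 in each comparison with an estimated correlation in camera, where 3, 1 and 2 lists had an unadjusted p under 0.05. For UC and CD they were 1 with ranks, where the inflammation-induced list was lost, 4 with totals alone, 4 without the 2 shallow libraries, and for the rest of the settings the count stayed within 1.5 times. The correlation of UC and CD changes was 0.34 and 0.32 with the controls split at random, and 0.47 with RLE scaling. The depth differences kept their side when the 3 most abundant miRNAs were left out.

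Of the named miRNAs past the threshold, 32 for UC and control, 25 for CD and control and 29 for UC and CD, none changed direction in any setting, and 13, 13 and 18 of them were not past it in at least 1. Those that did change direction were not past it to begin with, and the cause was not tested. For UC and control, limma-voom gave −0.42 for mir-1-2 and −0.53 for mir-1-1, and upper-quartile scaling gave −0.00 for mir-1826 and −0.09 for mir-1-1. Leaving out single libraries gave −0.19 to 0.31 for mir-1826, −0.15 to 0.40 for mir-1-2 and −0.47 to 0.37 for mir-1-1. For CD and control, totals alone gave 0.11 for mir-155, 0.32 for mir-196b, 0.20 for mir-7-1, 0.03 for mir-16-2 and 0.30 for mir-196a-1. Single libraries left out gave −0.49 to 0.03 for mir-196a-1 and −0.50 to 1.13 for mir-363. For UC and CD, limma-voom gave 0.13 for mir-143, 0.29 for mir-196b and −0.38 for mir-125b-2, and single libraries left out gave −0.38 to 0.37 for mir-143 and −0.17 to 0.97 for mir-125b-2. Depth limits hairpins with few reads, and 320 with reads were not tested.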

Other observations

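The tests in this part were chosen after the result was seen, except those of mir-655 and mir-432, which belong to the planned comparison of CD and control. Outside the naming rule, mir-194-1 was chosen after its values were seen.

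In the mir-194 pair, which yields the same mature sequence from chromosome 11 and from another locus, the log2 difference of mir-194-2 and mir-194-1 was 1.86 ± 1.04 in UC and 3.38 ± 1.46 in controls (difference −1.52, permutation test, adjusted p = 0.0203). Against controls CD differed by 0.072 (exact permutation test, adjusted p = 0.928), and UC and CD differed by −1.59 (exact permutation test, adjusted p = 0.155). Between the 2 libraries of UC replicate 3, mir-194-2 moved by −1.17 and mir-194-1 by 0.60, which shifts their difference by more than UC and controls differed, so nothing is drawn from it. How reads that match both loci were assigned is not stated. The 14q32 hairpins that passed in CD all rose, mir-655 by 1.48 ± 0.28 and mir-432 by 0.92 ± 0.23 against controls.

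Entries known as pieces of structural RNA were looked at before the snoRNA regions, and that pattern was then replaced by the snoRNA pattern. Of 4 such entries tested in CD against control, 2 were higher and 0 lower, with a median change of 0.63, which ran from −0.11 to 1.36 when each was left out in turn, so the median decides nothing. After thinning mir-1826 was at 1.93 and mir-1975 at 1.48, both still past the threshold.

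UC replicate 3 is the only sample with 2 libraries, of 3629380 and 4608920 reads. Over 228 miRNAs with at least 100 reads the median absolute log2 difference between them was 0.47, and 47 miRNAs were over 2-fold apart. The difference had r = −0.12 with the UC change, 0.08 with the CD change and −0.20 with the difference of UC and CD, across miRNAs.

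Reads in the deposited regions made up 84.3% of the total observations that the file headers give for UC, 95.0% for controls and 73.0% for CD. Among all reads in regions, snoRNAs took 3.48% ± 0.976 in UC, 3.25% ± 1.89 in CD and 2.35% ± 0.966 in controls. The share was higher in UC than in controls (permutation test, adjusted p = 0.0214), and for CD the exact permutation test gave an adjusted p of 0.168. The first 3 principal components of the miRNA levels held 17.2%, 12.8% and 9.90% of the variance.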
